A study of Oryza sativa and Arabidopsis thaliana with 16 samples.

How the data were processed

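Gene expression was measured with 1-colour Affymetrix arrays in wild-type rice (Oryza sativa) and Arabidopsis (Arabidopsis thaliana) seedlings. In each of the 2 species, 2 tissues (root and shoot) were compared between nitrogen-treated and control plants, which gave 8 groups of 2 arrays and 16 arrays in all. Per the labels, the arrays of a group are biological replicates. Per the labels' protocols, plants grew hydroponically, with ammonium succinate at 0.5 mM as nitrogen source and sucrose at 3 mM, rice at 27 °C and a light intensity of 180 μE per second and square metre, Arabidopsis at 22 °C and 50 μE. On day 13, at the start of the light period, treated plants received KNO3 and NH4NO3, each at 20 mM, for 2 h and control plants 20 mM KCl. Treated plants thus also differed from controls in chloride and in the amount of added salt. What is called the nitrogen response below cannot be told apart from these. The labels are not of 1 mind on the material: the treatment and extraction protocols speak of whole seedlings or plants, while the titles and the tissue label of each sample say root or shoot. Groups follow the tissue label.

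The deposited values are log2 expression values per probe set, and per the submitters' processing notes they were made with RMA (robust multi-array average, which corrects the background, normalizes across arrays and summarises the probes of a set). The version of RMA, and whether the arrays of each species were processed in 1 run, are not given in the sources used here. The deposited log2 values were used with no further transformation or scaling. Every column of the value tables belonged to 1 sample of the series. The precision of every estimate is limited by the number of arrays, and RMA values carry no detection call.

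Control probe sets were left out (123 of 57381 for rice and 64 of 22810 for Arabidopsis). Probe sets were named from the platform annotation. Of the 57258 rice probe sets tested, 22436 had 1 gene, 95 several and 34727 were not paired with a gene there. Of the 22746 Arabidopsis probe sets, 13513 had 1 gene, 503 several and 8730 none in that table. Rice gene numbers were given symbols through a RefSeq gene table of assembly ASM3414082v1, used for names alone. A name other than a locus or gene number was found for 2449 of 17905 rice genes and 1552 of 13350 Arabidopsis genes. Probe sets with several genes are not named.

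Each species was fitted on its own with limma 3.58.1 in R 4.3.3. The linear model had 4 group means over the 8 arrays (4 residual degrees of freedom) and moderated variances (eBayes). Contrasts were nitrogen against control in root, in shoot and on average over the tissues, the difference between the root and shoot responses (interaction), and root against shoot. P values are two-sided and adjusted by the Benjamini-Hochberg method over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Changes are differences of log2 means with their standard error. Signal was never compared across the species' different arrays.

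Gene lists were tested with camera (preset inter-gene correlation 0.01), with camera at an estimated correlation and with fry, on the probe set of highest mean per gene. Camera compares a list with all other genes, and fry asks whether its members move, on balance, one way. A call lost with an estimated correlation is not by itself a sign that the genes of a list move together. Nor does such a loss argue against a list here. That form of camera passed neither photosynthesis list between the tissues, although every measured member was lower in roots. In rice shoots the estimated correlation was 0.0162 for glutaredoxins, near the preset, and -0.190 for nitrate genes. Their camera adjusted p still rose, from 0.0321 to 0.388 and from 0.00710 to 0.358. Lists with fewer than 3 measured members were given as values. The groups, tests, alternatives, gene lists and the naming rule were fixed before the data were examined. The annotation held symbols but no descriptions. List members were therefore matched by symbol or locus code after the annotation had been seen and before any nitrogen response was computed. As a result, the rice glutaredoxin list also holds members of other glutaredoxin classes. Most rice nitrogen-linked regulators are TGA-type genes taken by name, and their link to nitrogen was not checked. The rice sulfate list holds only serine acetyltransferase (SAT) genes, with no sulfate transporter or reductase gene. Nitrate and nitrite reductase, NRT2.1, asparagine and glutamine synthetase, the AMT1 transporters, glucose-6-phosphate dehydrogenase and the LBD37 to LBD39 regulators of Arabidopsis are not named by the annotation used here and are not reported.

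The 17 lists were nitrate uptake and reduction, ammonium uptake and assimilation, the pentose phosphate pathway with root-type ferredoxin reduction, organic acid synthesis, nitrogen-linked regulators, cytokinin synthesis and response, sulfate uptake and reduction, phosphate starvation, iron uptake, CC-type glutaredoxins (in rice taken by GRX name, with their class not checked), ribosomal proteins, aminoacyl-tRNA synthetases, photosynthesis, root markers, osmotic and abscisic acid response, touch and wound response, and heat shock proteins. The naming rule took, per species and tissue, the 8 named genes with the largest called rise and the 8 with the largest called fall, both nitrogen arrays lying on the same side of both control arrays. It further took up to 4 members of each list by adjusted p, a fixed set of nitrogen assimilation genes, 5 genes per direction for the interaction and 4 per tissue for root against shoot. Because most Arabidopsis entries are locus codes, the 8 largest rises and falls among locus codes were added at the same stage as the list members.

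Conservation was examined by the sign and call of each list in both species, and by families of genes that share the letters at the start of their name. These families stand in for families by description, and were chosen at the same stage as the list members. Overlaps of called families were tested with 10000 one-sided permutations of calls among genes within species. Sequences were not used here.

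The model was tested on simulated data with known changes added. The noise was independent and normal, with 1 moderated variance per probe set for all 8 arrays of a species. At a log2 change of 1 it recovered 91.0% of 67 changed probe sets for the rice root response, 94.0% for the rice shoot response, 58.2% for the Arabidopsis root response and 55.2% for the Arabidopsis shoot response. At a change of 0.5 it recovered 8.96%, 13.4%, 1.49% and 1.49% in the same order. At a change of 2 it recovered 100%, 100%, 93.9% and 98.5% of 66. Calls of unchanged probe sets in the same fits numbered 12, 15, 3 and 8. They are to be read against the recovered probe sets rather than against all that were tested. In the real Arabidopsis arrays the standard deviation of the replicate difference was 0.49 in root controls and 0.21 in shoot controls. The simulated rates may therefore not hold for Arabidopsis.

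The same comparisons were also run with a replicate block, leaving out dim probe sets (mean below the 40th percentile), quantile normalization of the deposited values, centring each array on its median, a trended and robust prior, no moderation, a minimum log2 change of 1, the arrays of 1 tissue alone, and leaving out each array in turn, and for gene lists with the mean of all probe sets of a gene. Array weights for Arabidopsis, and the scaling and left-out-array checks of the gene lists and families, were added after the data had been seen. The replicate numbers in the labels are not tied to shared plants, trays or days, so the arrays were not treated as pairs.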

Results

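The series asks how far the early nitrogen response is shared between rice and Arabidopsis. Roots and shoots of 13-day-old seedlings were profiled 2 h after nitrate and ammonium were added together, or after KCl in controls. Values are RMA log2 signal, with 2 arrays in each of the 8 groups. In rice the arrays of a group correlated across probe sets at 0.993 to 0.994. In Arabidopsis the correlation was 0.956 between the root control arrays, 0.987 between root nitrogen arrays, 0.993 between shoot control arrays and 0.981 between shoot nitrogen arrays. The standard deviation of the difference between the arrays of a pair was 0.49 for Arabidopsis root controls and 0.21 for shoot controls. The Arabidopsis root control arrays also had a narrower range of values. Their 75th percentile was 6.92 and 6.83 against 7.22 and 7.20 in root nitrogen arrays and 7.16 and 7.18 in shoot controls. Their 25th percentile was higher, at 4.69 and 4.75 against 4.53 and 4.54 in root nitrogen arrays and 4.56 in each shoot control array.

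In rice roots, nitrogen raised single genes for nitrate reductase, for enzymes that supply reducing power and for hemoglobins. The largest rises among named genes were those of the non-symbiotic hemoglobins, which scavenge nitric oxide. NSHB2 (LOC4332123) rose by 3.01 ± 0.14 (log2 change ± SE, n = 2 arrays per group; adjusted p = 0.000506) and NSHB1 (LOC4332166) by 2.71 ± 0.16 (adjusted p = 0.00158). Nitrate reductase NIA1 (LOC4345795) rose by 1.75 ± 0.23 (adjusted p = 0.0336), 6-phosphogluconate dehydrogenase G6PGH2 (LOC4350528) by 1.69 ± 0.16 (adjusted p = 0.0114) and the ferredoxin-NADP reductase FNR (LOC4334338) by 1.55 ± 0.17 (adjusted p = 0.0172). Trehalose-phosphate phosphatase TPP1 rose by 2.27 ± 0.22, the protein kinase gene CIPK14 by 1.58 ± 0.15 and the germin-like gene GER3 by 1.55 ± 0.15. Of the named genes 3 fell: the auxin transporter gene PIN5 by 2.03 ± 0.19, the calmodulin-like gene CML10 by 1.22 ± 0.15 and the cytochrome P450 gene CYP714C2 by 0.82 ± 0.12. In all, limma called 140 of 57258 probe sets, 104 higher and 36 lower. Without root nitrogen replicate 2 the calls were 81 higher and 112 lower, so no direction is given for the response as a whole.

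Of the 4 measured genes of the pentose phosphate and ferredoxin reduction list, G6PGH2 and FNR rose in rice roots, also when adjusted over the list alone. G6PGH1 (-0.16) and a second FNR gene (LOC4342399, 0.03) were not called. The list lay above other genes (camera adjusted p = 0.0287), and with an estimated correlation the adjusted p was 0.802. The 16 nitrogen-linked regulators also lay above other genes (median log2 change 0.17, adjusted p = 0.0287, and adjusted p = 0.802 with an estimated correlation). None of the regulators was called over all probe sets, and 3 were when adjusted over the list alone: TGAL5 (1.51 ± 0.25), TGAL8 (1.02 ± 0.15) and TGAL1 (0.54 ± 0.10). These encode TGA-type transcription factors, the type of most of the rice list, whose link to nitrogen was not checked. Without root control replicate 1 the regulators' adjusted p was 0.186. Fry passed neither list (adjusted p = 0.111 for each). Nitrate transport genes were not called: NRT2.2 changed by 0.32 ± 0.13, NRT2.3 by -0.76 ± 0.23 and NAR2.2 by -0.18 ± 0.13, while adjusted over the list alone 2 of the 4 nitrate genes were higher and 1 lower. None of the 17 ammonium genes was called (camera adjusted p = 0.863), and adjusted over the list alone 2 were higher and 1 lower. GLN2 (glutamine synthetase) was at 0.73 ± 0.17, GDH2 (glutamate dehydrogenase) at 1.21 ± 0.34 and GLN1-3 at -0.51 ± 0.15.

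Among the other lists in rice roots, GRXS9 rose by 0.78 ± 0.10 out of 15 glutaredoxins, and CML16 rose by 0.88 ± 0.10 while CML10 fell among 39 touch and wound genes. No member was called among 11 cytokinin genes, 4 sulfate genes (SAT genes only), 15 phosphate starvation genes, 23 iron uptake genes and 24 ribosomal proteins. The same held for 3 aminoacyl-tRNA synthetases, 9 photosynthesis genes, 5 root markers, 14 osmotic response genes and 23 heat shock proteins. Adjusted over the list alone, 3 cytokinin genes, 2 phosphate starvation genes and the osmotic response gene OsPP2C09 were higher, and 2 iron uptake genes and the root marker PRX112 lower. In the same way 3 glutaredoxins were higher and 1 lower, and 1 touch and wound gene was higher and 2 lower. The camera adjusted p of these lists lay between 0.0523 (osmotic response) and 0.862. After quantile normalization the osmotic response list passed camera (higher, adjusted p = 0.0265). The single organic acid gene measured changed by 0.08.

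The count of rice root calls was 20 with the root arrays alone and 0 without moderated variances (limma, with 6019 probe sets at an unadjusted p under 0.05 in the moderated fit). It was 32 without root control replicate 1, 18 without root control replicate 2, 42 without root nitrogen replicate 1, and 66 without either of the shoot nitrogen arrays. Of the 13 called named genes only NSHB2 and NSHB1 were called in each fit that left out 1 array.

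In rice shoots the same hemoglobin, nitrate reductase and reducing-power genes led the response among named genes. NSHB2 rose by 2.43 ± 0.14 (adjusted p = 0.00281), NIA1 by 2.07 ± 0.23 (adjusted p = 0.0427), FNR (LOC4334338) by 1.95 ± 0.17 (adjusted p = 0.0136), NSHB1, here by another of its probe sets, by 1.92 ± 0.16 (adjusted p = 0.0110) and G6PGH2 by 1.78 ± 0.16 (adjusted p = 0.0155). The calmodulin-like gene CML16 rose by 1.20 ± 0.10, monodehydroascorbate reductase MDAR5 by 1.14 ± 0.11 and the laccase gene LAC19 by 1.12 ± 0.11. Limma called 25 probe sets, all of them higher. Without shoot control replicate 2 the calls were 9 higher and 13 lower, so the single direction did not hold in each such fit. The count was 3 with the shoot arrays alone and 1 without moderated variances. It was 12 without either root control array, 11 without shoot control replicate 1, 5 without shoot nitrogen replicate 1 and 14 without shoot nitrogen replicate 2. Of the 8 called named genes only NSHB2 was called in each fit that left out 1 array.

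The pentose phosphate and ferredoxin reduction list was higher in rice shoots (median log2 change 1.06, camera adjusted p = 3.56e-05, and adjusted p = 0.358 with an estimated correlation). Of its 4 members 2 rose, and 3 were higher when adjusted over the list alone. The 4 nitrate genes lay above other genes (camera adjusted p = 0.00710, and adjusted p = 0.358 with an estimated correlation) with NIA1 as the called member, also when adjusted over the list alone. Without shoot nitrogen replicate 2 the adjusted p of the nitrate list was 0.0551. Fry also passed these lists (adjusted p = 0.0360 for pentose phosphate and 0.0193 for nitrate genes), and not the glutaredoxins (0.155) or the regulators (0.228). The glutaredoxin list was higher (camera adjusted p = 0.0321, and adjusted p = 0.388 with an estimated correlation); none of its 15 members was called over all probe sets, and GRXC10 (1.62 ± 0.23), GRXC1 (1.02 ± 0.18) and GRXC15 (0.97 ± 0.23) were when adjusted over the list alone. The glutaredoxin adjusted p was 0.101 without shoot control replicate 2 and 0.193 without shoot nitrogen replicate 1, and 0.0595 after quantile normalization. The nitrogen-linked regulators were higher at a camera adjusted p of 0.0480 (adjusted p = 0.650 with an estimated correlation), with NIGT1, a repressor of the nitrate response, at 0.53 ± 0.11 and called when adjusted over the list alone. The regulators' adjusted p was 0.353 without shoot control replicate 1, 0.0548 without shoot control replicate 2, 0.118 and 0.193 without shoot nitrogen replicates 1 and 2, 0.0800 without either of the root nitrogen arrays, and 0.0796 after quantile normalization.

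Another 5 lists passed the camera threshold in rice shoots and none of them passed fry (adjusted p from 0.192 to 0.920). Heat shock proteins (median log2 change 0.14, adjusted p = 0.0232), osmotic response genes (0.26, adjusted p = 0.0321) and touch and wound genes (0.09, adjusted p = 0.0325) were higher, and with an estimated correlation the adjusted p of each was 0.650. Ribosomal proteins (-0.12, adjusted p = 0.0232, and adjusted p = 0.739 with an estimated correlation) and root markers (-0.62, adjusted p = 0.0453, and adjusted p = 0.650 with an estimated correlation) were lower. CML16 was the called member of these lists, and adjusted over the list alone it was joined by LOX9, CML31 and CML14. Heat shock proteins had an adjusted p of 0.866 without shoot nitrogen replicate 1 and 0.0783 without shoot control replicate 2, and osmotic genes 0.906 without shoot nitrogen replicate 1 and 0.238 without shoot control replicate 1. Ribosomal proteins had 0.816 without shoot control replicate 1, where the sign turned, and 0.548 without shoot nitrogen replicate 2. Root markers had 0.265, 0.0548 and 0.301 without shoot control replicates 1 and 2 and shoot nitrogen replicate 2, and 0.0796 after quantile normalization, and touch and wound genes 0.265 and 0.577 without shoot control replicate 1 and shoot nitrogen replicate 2. The remaining lists (ammonium, cytokinin, sulfate, phosphate starvation, iron, aminoacyl-tRNA synthetases and photosynthesis) had adjusted p between 0.254 and 0.870, and the organic acid gene changed by 0.09. Of these, NAAT1 of iron uptake (0.50) was higher when adjusted over the list alone.

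The rice response was not shown to differ between tissues. Of the 104 probe sets higher in roots, 20 were also among the 25 higher in shoots, where independent lists would share 0.0454. The root and shoot calls of a probe set share 1 variance estimate, so they are not independent and the excess may be overstated. The 20 included NSHB2, NIA1, FNR (LOC4334338), G6PGH2, MDAR5 and LAC19. No probe set passed the interaction test with limma, 3450 had an unadjusted p under 0.05, and the model without moderated variances also called 0. TPP1, for instance, was at 2.27 in roots and -0.22 in shoots (interaction adjusted p = 0.279). The average over both tissues called 76 probe sets, 66 higher and 10 lower. The balance was 49 higher and 37 lower without root nitrogen replicate 2 and 52 higher and 31 lower without shoot control replicate 2. That count was 1 without moderated variances, 44 without root control replicate 1 or root nitrogen replicate 1, 36 without root control replicate 2, 34 without shoot control replicate 1, and 35 and 32 without shoot nitrogen replicates 1 and 2.

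**Figure D1:**
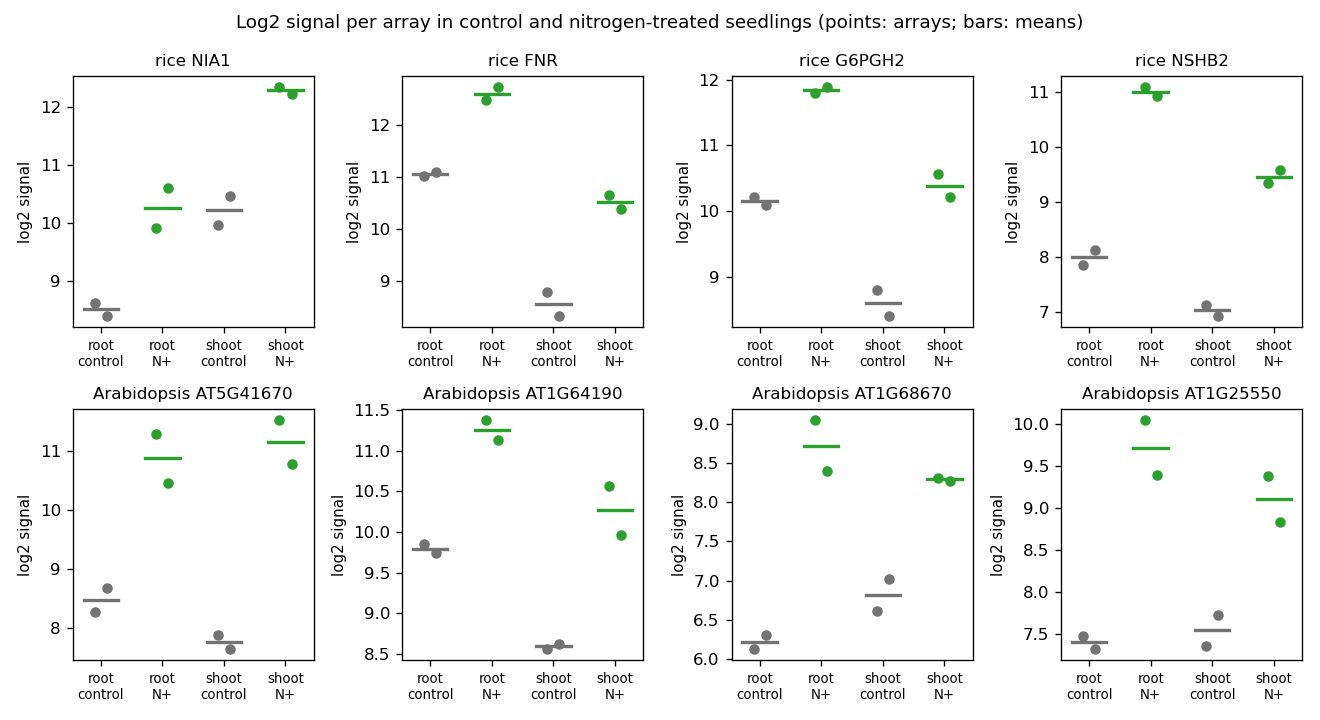
Log2 signal on each array (points) and group means (bars) for 4 rice and 4 Arabidopsis genes, by tissue and treatment, with a separate vertical axis per gene. In roots and in shoots both nitrogen arrays lay above both control arrays for each gene, as for rice NSHB2, which rose by 3.01 in roots and 2.43 in shoots.

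In Arabidopsis roots, the rises included single genes for a sugar transporter, phosphoglucomutase and a glutamine amidotransferase, and regulators of the HRS1/HHO group. Among named genes the serine carboxypeptidase-like gene scpl31 rose by 3.70 ± 0.17 (adjusted p = 0.00186), the glutamine amidotransferase gene GAT1_2.1 by 3.29 ± 0.29 (adjusted p = 0.00472), the kinase gene WNK7 by 2.53 ± 0.34 (adjusted p = 0.0115) and phosphoglucomutase PGM by 2.11 ± 0.46 (adjusted p = 0.0342). The ubiquitin ligase gene ATL8 rose by 1.86 ± 0.20, the lipase gene SDP1 by 1.84 ± 0.27, the vacuolar sugar transporter gene TMT1 by 1.84 ± 0.38 and the glucosinolate glucosyltransferase gene UGT74B1 by 1.77 ± 0.16. Among genes given by a locus code, AT1G49500 rose by 4.36 ± 0.29, AT3G07350 by 3.53 ± 0.27, AT3G16560 by 3.18 ± 0.22, AT1G80380 by 3.18 ± 0.26 and AT5G18840 by 3.13 ± 0.23. Among named genes the largest falls were those of the organic cation transporter gene OCT1 (-2.47 ± 0.42), SUFE2 (-2.44 ± 0.12) and the expansin gene EXPA9 (-1.64 ± 0.28). Next came SBPASE of the Calvin cycle (-1.40 ± 0.24), scpl40 (-1.32 ± 0.28), CYP71B16 (-1.31 ± 0.12), EC1.2 (-1.27 ± 0.13) and AER (-1.27 ± 0.26). By locus code AT4G17670 fell by 2.55 ± 0.25, AT5G52720 by 2.46 ± 0.40, and AT1G64590 fell too (adjusted p = 0.00693). Called falls numbered 1011 over all probe sets and 186 with dim probe sets left out, against 1578 and 1161 called rises. Which of the falling genes were dim is not given here. Probe sets not paired with a gene made up 737 of the called rises and 305 of the called falls. Among them, 1 rose by 4.70 ± 0.28, more than any gene given here.

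Of the 3 regulators measured, all of the HRS1/HHO group that represses nitrate uptake genes, 2 rose in Arabidopsis roots: AT1G25550 by 2.32 ± 0.27 (adjusted p = 0.00856) and AT1G68670 (adjusted p = 0.00514). AT3G25790 was at -0.08. Of 4 pentose phosphate genes, the 6-phosphogluconate dehydrogenase genes AT5G41670 (2.42 ± 0.34) and AT1G64190 (1.46 ± 0.21) rose, each with an adjusted p of 0.0126. IDH-V, an isocitrate dehydrogenase subunit, rose by 0.67 ± 0.17 among 5 organic acid genes, sulfite reductase SIR by 1.15 ± 0.25 among 3 sulfate genes, and AT1G47400 by 1.70 ± 0.22 among 3 iron genes. ROXY2 rose by 1.12 ± 0.11 among 14 glutaredoxins, 1 of 118 ribosomal proteins (AT1G23410, 0.90 ± 0.18) rose, and PSB27 of photosystem II rose by 1.63 ± 0.26 among 8 photosynthesis genes. Of 48 root markers, AT5G06730 rose by 0.96 ± 0.13 and AT2G39040 (-1.06 ± 0.17), AT3G49960 (-1.05 ± 0.19) and AT5G58400 (-0.92 ± 0.22) fell. Adjusted over the list alone, the counts were the same for regulators, pentose phosphate, organic acid, sulfate, glutaredoxin and photosynthesis genes, 2 for iron, 0 for ribosomal proteins (limma) and 1 higher and 2 lower for root markers. No list passed camera in Arabidopsis roots (adjusted p from 0.107 to 0.902), nor did any of the 4 osmotic response genes or 10 heat shock proteins. Fry passed 3 lists there: iron (adjusted p = 0.00875), regulators (0.00943) and pentose phosphate (0.0265). After quantile normalization 3 lists passed camera: regulators (higher, adjusted p = 0.00899), ribosomal proteins (lower, 0.00899) and root markers (lower, 0.0147). The high-affinity nitrate transporter NRT2.5 changed by -0.24 ± 0.26. STZ, the touch and wound gene measured, changed by 0.24, and the phosphate gene by 0.29. No ammonium gene or aminoacyl-tRNA synthetase of Arabidopsis is named by the annotation used here.

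Limma called 2589 of 22746 Arabidopsis probe sets in roots, 1578 higher (61.0%) and 1011 lower. With each array centred on its median there were 1102 higher and 1596 lower (40.8% higher), so no direction is given for the response as a whole. The count was 1212 after quantile normalization, of which 1074 were among the 2589, 270 with array weights and 0 with the root arrays alone. It was 6122 without root control replicate 1, 124 and 153 without root nitrogen replicates 1 and 2, 689 without either shoot control array and 1505 without either shoot nitrogen array. Of 46 called named genes 18 were called in each fit that left out 1 array, among them scpl31, GAT1_2.1, ATL8, UGT74B1, AT1G49500, AT1G80380, AT1G68670, SUFE2 and CYP71B16.

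In Arabidopsis shoots the rises included 6-phosphogluconate dehydrogenase, phosphoglucomutase and a glutaredoxin of the CC class. AT5G41670 rose by 3.39 ± 0.34 (adjusted p = 0.0123) and AT1G64190 by 1.67 ± 0.21 (adjusted p = 0.0258). PGM rose by 3.10 ± 0.46, the metallothionein gene MT1C by 2.89 ± 0.29, the phosphoethanolamine methyltransferase gene PMEAMT by 2.14 ± 0.27 and the ubiquitin-conjugating enzyme gene UBC18 by 1.31 ± 0.19. By locus code AT1G49500 rose by 4.05 ± 0.29, AT2G41730 by 3.49 ± 0.28, AT3G19030 by 3.36 ± 0.37, the CC-type glutaredoxin AT4G15690 by 2.46 ± 0.17 (adjusted p = 0.00358) and AT5G51440 of the heat shock list by 2.43 ± 0.31. Falls were those of the cation exchanger gene CHX16 (-1.56 ± 0.22), PAP85 (-1.53 ± 0.14), the sucrose-phosphate synthase gene ATSPS4F (-1.37 ± 0.17), ATIM (-1.12 ± 0.14), MYBC1 (-1.12 ± 0.16), the transcription factor gene WRKY22 (adjusted p = 0.0288) and BGLU46 (-0.94 ± 0.13). AT3G26510 fell by 2.52 ± 0.18 and AT4G01460 by 1.73 ± 0.12. Probe sets not paired with a gene made up 54 of the 85 called rises and 25 of the 60 called falls. Among them, 2 rose by 6.33 ± 0.20 and 5.99 ± 0.28, more than any gene given here.

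The CC-type glutaredoxins were higher as a list in Arabidopsis shoots (median log2 change 0.57, camera adjusted p = 2.29e-11, and adjusted p = 0.119 with an estimated correlation). Of 14 measured, 1 was called over all probe sets and 6 when adjusted over the list alone, including the neighbours AT4G15680 (2.28 ± 0.41), AT4G15700 (1.58 ± 0.30) and AT4G15660. Such near-identical copies may share probe signal on a 3' array. The regulators (camera adjusted p = 1.76e-05), pentose phosphate genes (adjusted p = 0.000148) and organic acid genes (adjusted p = 0.00174) were higher too, and with an estimated correlation the adjusted p of each was 0.0924. AT1G25550 (1.57 ± 0.27) and AT1G68670 (1.48 ± 0.24) were not called over all probe sets (adjusted p = 0.0822 and 0.0602) and were when adjusted over the list alone, as were the isocitrate dehydrogenase genes IDH-V (1.08 ± 0.17) and cICDH (0.65 ± 0.18). The pentose phosphate count was 2 of 4 over all probe sets and adjusted over the list alone. Without shoot nitrogen replicate 1 the organic acid adjusted p was 0.0565. Fry passed all 4 lists (adjusted p = 0.0358 for the glutaredoxins and 0.0234 for each of the others). AT5G51440 was the called member of 10 heat shock proteins, also when adjusted over the list alone (camera adjusted p = 0.0745). The other lists (sulfate, iron, ribosomal, photosynthesis, root markers and osmotic response) had adjusted p between 0.245 and 0.619 with no called member. Adjusted over the list alone, SIR and the root marker AT5G39580 (1.76 ± 0.31) were higher. STZ (1.81 ± 0.53) and NRT2.5 (-0.78 ± 0.26) were the only measured members of their lists. Their limma p under 0.05 was therefore not adjusted at all, and neither was called over all probe sets. The phosphate gene measured was at -0.19, and the median of the 2 cytokinin genes was 0.49 in shoots and 0.06 in roots.

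Limma called 145 probe sets in Arabidopsis shoots, 85 higher and 60 lower. The count was 62 with the shoot arrays alone, 406 with array weights and 0 without moderated variances (limma, with 1566 probe sets at an unadjusted p under 0.05 in the moderated fit). It was 5 without either shoot control array, 67 without either root nitrogen array and 77 without shoot nitrogen replicate 2. None of the 28 called named genes was called without a shoot control array.

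By the interaction test the response of some Arabidopsis genes differed between the tissues, on calls that single arrays ended. Scpl31 (interaction 3.57 ± 0.24, adjusted p = 0.0230), GAT1_2.1 (3.07 ± 0.41, adjusted p = 0.0482), the histone gene HON4 (1.32 ± 0.18, adjusted p = 0.0496), SAMTL (1.89 ± 0.25) and ARLA1A (1.20 ± 0.16) had the larger change in roots, and SUFE2 (-1.99 ± 0.18, adjusted p = 0.0316), GT72B1 (-2.42 ± 0.35), EC1.2 (-1.30 ± 0.18) and CYP71B16 (-1.28 ± 0.17) the lower. The interaction called 110 probe sets, 78 positive and 32 negative. The balance turned with a trended robust prior (105 positive, 177 negative) and without shoot nitrogen replicate 1 (34 positive, 58 negative). With arrays centred on their medians it called 42, 23 positive and 19 negative, and centring moved the median of all interaction values by -0.11. The count was 24 after quantile normalization and 27 with array weights. It was 3178 and 1469 without root control replicates 1 and 2, 5 without shoot nitrogen replicate 2, and 0 without any 1 of the root nitrogen or shoot control arrays (limma, with 4305 at an unadjusted p under 0.05 with all arrays, and 34 called without moderated variances).

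Across tissues, 54 probe sets were higher in both Arabidopsis roots and shoots (independent expectation 5.90) and 13 lower in both (2.67), while 6 that were higher in roots were lower in shoots. Here too the calls of both tissues share 1 variance estimate per probe set, so the excess may be overstated. Genes higher in both included AT1G49500, AT5G41670, AT1G64190, PGM, PMEAMT and UBC18, and AT1G64590 and AT4G17670 were lower in both. The average over tissues called 730, 494 higher and 236 lower, or 363 higher and 279 lower with centred arrays and 464 higher and 508 lower with a trended robust prior. That count was 438 after quantile normalization and 434 with array weights. It was 3769 and 2304 without root control replicates 1 and 2, 124 and 184 without root nitrogen replicates 1 and 2, 81 and 74 without shoot control replicates 1 and 2, and 466 and 282 without shoot nitrogen replicates 1 and 2.

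Most tissue markers followed the labels. All 9 rice and all 8 Arabidopsis photosynthesis genes were lower in roots (median log2 difference -3.75 and -5.47), and all 5 rice root markers were higher (3.19). Of 48 Arabidopsis root markers 27 were higher in roots, 5 lower and 16 not called. The rice root markers did not pass camera (adjusted p = 0.0590), and the Arabidopsis ones did (9.65e-05, and adjusted p = 0.345 with an estimated correlation). Camera gave these photosynthesis lists adjusted p of 2.56e-05 and 4.63e-10, and adjusted p of 0.747 and 0.172 with an estimated correlation. The rankings that follow hold among named genes alone. Rice roots exceeded shoots most in the nicotianamine synthase genes NAS1 (7.61 ± 0.66) and NAS2 (6.52 ± 0.39), the aquaporin gene TIP2-1 (6.43 ± 0.49) and the silicon efflux transporter gene Lsi2 (6.17 ± 0.10). Rice shoots led in LFNR1 (-6.43 ± 0.31), Pi21 (-6.39 ± 0.21), GDCSH (-6.01 ± 0.16) and ALDP (-5.94 ± 0.24). Arabidopsis roots led in the dehydrin gene LTI30 (4.48 ± 0.20), MSRB5 (4.31 ± 0.15), SBT4.12 (4.00 ± 0.19) and EXLB1 (3.78 ± 0.20), and shoots in LHCB4.2 (-5.94 ± 0.20), PRK (-5.76 ± 0.15), HPR (-5.73 ± 0.11) and PSBY (-5.62 ± 0.11). The tissues differed at 22888 rice and 8141 Arabidopsis probe sets (13936 and 4394 higher in roots).

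Genes for 6-phosphogluconate dehydrogenase of the pentose phosphate pathway were called higher in roots and shoots of both species. Rice G6PGH2 was at 1.69 in roots and 1.78 in shoots, and Arabidopsis AT5G41670 at 2.42 and 3.39. Of the 8 fits that left out 1 array, G6PGH2 lost its call in 3 for roots and 6 for shoots, and AT5G41670 in 1 for roots and 2 for shoots. Of 10 lists tested in both species, camera gave the same direction for 6 in roots and 9 in shoots, whether called or not. In shoots 3 lists were higher in both species by camera: pentose phosphate and ferredoxin reduction genes, glutaredoxins and nitrogen-linked regulators. Their members are not matched genes: the regulators were mostly TGA-type in rice (16 genes) and all of the HRS1/HHO group in Arabidopsis (3 genes). With an estimated correlation the adjusted p of these 3 lists was 0.358, 0.388 and 0.650 in rice and 0.0924, 0.119 and 0.0924 in Arabidopsis. None of the calls held in that form of camera, not even for rice glutaredoxins, whose estimated correlation of 0.0162 was near the preset. It did not pass the photosynthesis lists between the tissues either, so it cannot decide about these calls. Single arrays ended the rice calls of the glutaredoxins and the regulators. In roots camera passed 2 lists in rice and 0 in Arabidopsis (lowest adjusted p 0.107), and fry 0 in rice (lowest adjusted p 0.111) and 3 in Arabidopsis.

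Families of like-named genes showed no excess of shared calls, but few were called in rice, so the test had little power. In roots 8 of 148 families had a rising member in rice and 28 in Arabidopsis, and 1 family, the glutaredoxins, was in both, where the permutations gave 1.91 on average (permutation p = 0.907, one-sided, adjusted p = 1). Of falling families 2 were called in rice and 9 in Arabidopsis, and 1, the cytochrome P450 genes, was in both (0.311 on average, permutation p = 0.291, adjusted p = 1). In shoots no family was shared: 3 in rice and 2 in Arabidopsis held a rising member (permutation p = 1), and 0 in rice and 4 in Arabidopsis a falling one (limma). The families cover 572 rice and 575 Arabidopsis genes, and most genes with a locus code or gene number were not among them. The 2 shared families became 0 without any 1 of the 8 rice arrays and 1 without either Arabidopsis root nitrogen array.

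**Figure D2:**
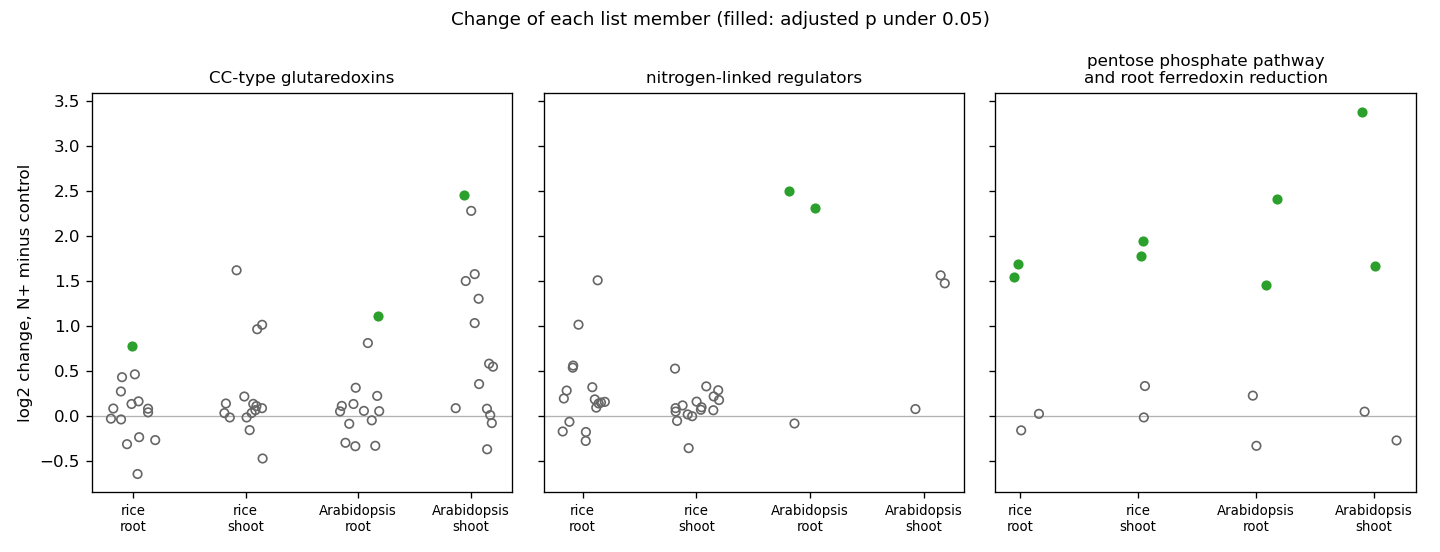
Log2 change with nitrogen (vertical axis) of each measured member of 3 lists in rice and Arabidopsis roots and shoots. Filled points passed an adjusted p of 0.05. The rice and Arabidopsis members of a list are not matched genes. In each of the 4 comparisons 2 of the 4 members of the pentose phosphate and ferredoxin reduction list were called higher (in rice G6PGH2 and an FNR gene, in Arabidopsis AT5G41670 and AT1G64190), while most glutaredoxins and rice regulators were not called.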

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

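Quantile normalization was planned for the counts. The tests with array weights, the tests of ratios and sizes after quantile normalization, and the comparison of splits alike in the other factor were chosen only after the results had been seen.

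Of the 110 Arabidopsis probe sets called by the interaction test between roots and shoots, those of 16 genes reported by name or locus code are given here. The difference (root change minus shoot change) was 3.57 for scpl31, 3.07 for GAT1_2.1, 2.99 for AT1G80380, 2.76 for AT5G18840, 2.19 for AT3G26510, 1.89 for SAMTL, 1.38 for AT4G01460, 1.32 for HON4 and 1.20 for ARLA1A. It was -1.28 for CYP71B16, -1.30 for EC1.2, -1.89 for AT3G32290, -1.99 for SUFE2, -2.32 for the CC-type glutaredoxin AT4G15690, -2.42 for GT72B1 and -3.70 for AT2G41730. AT4G15690 and AT2G41730 rose in shoots (2.46 and 3.49) and were at 0.14 and -0.20 in roots. AT1G80380 rose by 3.18 in roots and was at 0.19 in shoots.

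The 9 of these genes that the interaction rule names were weighed against properties of the arrays. A narrower range of values of the root control arrays cannot be told apart from a response. After quantile normalization the median size of the 9 differences was 0.970 of that in the deposited values (1.83 against 1.89, with a median SE of 0.19 against 0.18), yet only 2 of the 9 kept their call, as the median adjusted p went from 0.0482 to 0.0667. Unequal precision of the arrays under 1 shared spread may account for part of the calls, but the test cannot decide it. With array weights 4 of the 9 genes passed. The 9 were chosen by passing this threshold, at a median adjusted p of 0.0482, so any small change of the fit could end calls. The weights left the median size at 1.89 and moved the median SE from 0.18 to 0.21 and the median adjusted p from 0.0482 to 0.0666. A tissue difference in the response itself was not separated from either and stays open.

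More probe sets were called in Arabidopsis roots (2589) than in shoots (145). The narrower range of the root control arrays does not account for the whole of it, since the ratio of root to shoot calls was still 10.2 after quantile normalization. Unequal precision of the arrays may: with array weights, which were 0.304 for each root control array and 1.91 for each shoot control array, the ratio was 0.665, from 270 root and 406 shoot calls. With the arrays of each tissue fitted alone, limma called 0 probe sets in roots and 62 in shoots (4901 and 2089 at an unadjusted p under 0.05), so the order of the counts turned there too. A broader response of roots is not excluded.

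Other splits of the 8 arrays of a species into 4 and 4 were fitted with the other factor kept in the model, 34 per comparison with the real one included, and only 1, the real one, gave as many calls in each. Only 18 of them put 2 arrays of each level of the other factor on both sides, as the real one does, and these are too few for a share under 0.05. The average nitrogen response called 76 probe sets in rice and the highest other split 8, and in Arabidopsis 730 and 110. Root against shoot called 22888 in rice and the highest other split 0 (limma), and in Arabidopsis 8141 and 110. The Arabidopsis split with 110 set the root control and shoot nitrogen arrays against the rest, which is the interaction. Apart from the interaction, the other splits leave the real factor out of the model, so its effect adds to the residual variance and can lower their calls. For the nitrogen and tissue comparisons their median residual variance was 1.10 and 1.96 times the real one in rice. In Arabidopsis it was 1.59 and 2.16 times. The comparison therefore cannot tell the real counts from chance.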

How the results depend on the processing

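The array weights, and all scaling and left-out-array checks of gene lists and families, were chosen only after the results had been seen. Where a group is left with 1 array, it is assumed to vary like the others. The cause of the changes below was not tested, except that a minimum change removes calls by construction.

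No named called gene changed sign under any alternative, but few fits could have changed one. Only rescaling or a left-out array could move a log2 change. The largest rises and falls were chosen with both nitrogen arrays on the same side of both control arrays, so leaving out 1 array could not turn them. The labels do not tie the replicate numbers to shared plants, trays or days. Correlations of replicate differences between groups ran from 0.0279 to 0.350 in rice, all positive, and from -0.425 to 0.391 in Arabidopsis. Whether rice arrays of the same number share a source is not settled. With a replicate block the counts were 402 (rice root), 52 (rice shoot), 635 (rice average), 1389 (Arabidopsis root), 91 (Arabidopsis shoot), 331 (Arabidopsis average), 0 (Arabidopsis interaction) and 7 rice lists. The rice lists lost with the block were pentose phosphate (adjusted p = 0.0629) and regulators (0.0508) in roots, and regulators and glutaredoxins in shoots (0.0525 each). The rice shoot calls with the block were 31 higher and 21 lower, and the rice average 330 higher and 305 lower. With the mean of all probe sets of a gene 8 rice lists were called, and the shoot regulators and root markers (adjusted p = 0.0829 each) and touch and wound genes (0.0701) were lost. Without moderated variances the counts were 0, 1 and 1 for rice root, shoot and average, and 1099, 0, 252 and 34 for Arabidopsis root, shoot, average and interaction. At a log2 change of at least 1 they were 93 (rice root), 32 (rice average), 6821 (rice root against shoot), 843 (Arabidopsis root), 200 (Arabidopsis average) and 3442 (Arabidopsis root against shoot). The arrays of the tissue alone gave 20 and 3 in rice root and shoot, and 0 and 62 in Arabidopsis. Quantile normalization gave 1212, 438 and 24 for Arabidopsis root, average and interaction, 7 Arabidopsis lists and 1 shared family. Centred arrays gave 42 for the Arabidopsis interaction and 1 shared family, and the trended robust prior 282 for that interaction (105 positive, 177 negative). Leaving out dim probe sets gave 1347 Arabidopsis root calls (1161 higher, 186 lower). Array weights gave 270, 406, 434 and 27 for Arabidopsis root, shoot, average and interaction. With an estimated correlation 0 of the 11 rice and 0 of the 4 Arabidopsis list calls remained. That form of camera also missed the photosynthesis difference between the tissues, so these losses decide nothing about the lists. Shared families numbered 4 at an adjusted p under 0.1 and 0 with at most 5 members.

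Leaving out 1 array, counts ran from 18 to 193 (rice root), 5 to 22 (rice shoot), 32 to 86 (rice average), 0 to 1 (rice interaction), 19666 to 21234 (rice root against shoot), 124 to 6122 (Arabidopsis root), 5 to 183 (Arabidopsis shoot), 74 to 3769 (Arabidopsis average), 0 to 3178 (Arabidopsis interaction), 6084 to 10174 (Arabidopsis root against shoot), 6 to 12 rice lists, 4 to 9 Arabidopsis lists and 0 to 3 shared families. The rice lists were 6 without shoot control replicate 1 and 7 without shoot control replicate 2 or shoot nitrogen replicate 2. The Arabidopsis lists were 9 without root nitrogen replicate 1 and 7 without shoot nitrogen replicate 2. The rice interaction had 1 call without either root nitrogen array.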

Other observations

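Apart from nitrogen, several of the gene groups differed between the tissues. In Arabidopsis 84 of 118 ribosomal proteins were higher in roots than in shoots and 0 lower (median log2 difference 0.60, camera adjusted p = 3.70e-13, and adjusted p = 0.565 with an estimated correlation). In rice 20 of 24 were higher in roots and 2 lower (median 0.69, camera adjusted p = 0.0590). The CC-type glutaredoxins were lower in Arabidopsis roots, 7 of 14 with none higher (limma; median -0.46, adjusted p = 0.00127, and adjusted p = 0.565 with an estimated correlation). Of the 39 rice touch and wound genes 22 were lower in roots and 7 higher (adjusted p = 0.0178, and adjusted p = 0.747 with an estimated correlation). Of 16 rice nitrogen-linked regulators 10 were higher in roots and 1 lower (adjusted p = 0.0299, and adjusted p = 0.747 with an estimated correlation).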
